A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

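RNA from 12 samples was labelled with Cy3 and hybridized to 1 array each, per the labels with the Agilent Low Input Quick Amp kit, and the groups and replicates follow the sample labels: wild type and the hsp31, hsp32 and hsp33 deletions with 3 arrays each. The deposited scanner files hold, for each of 15736 spots, the foreground and local background intensity, neither normalized nor background-subtracted, and the deposited percent of saturated pixels. The authors' deposited series values are an intensity as well, equal to the median foreground in every spot of all 12 arrays. The authors' deposited comparison tables hold a ratio per spot, a unit listed here as other, and an unadjusted p value (p_value) from a test that is not stated. Scanner, software version and any normalization by the authors are not stated. The depth of an array is its brightness over background: median foreground 607 to 1153 and median local background 66 to 93. The threshold from the negative controls lay between 35.4 and 53.6 on 11 arrays and at 284 on hsp32 deletion replicate 2, where 80.3% of probes were detected. The number of arrays limits the precision.

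Of the spots 12504 carry genes, 536 are controls and 2696 are empty, and 6252 probes with 1 locus each are spotted on them; 5753 matched the reference table of loci and names and 499 did not. The design fixed before the data were examined named a processed signal, scaled to each array's 75th percentile, and a detection call. The files lack both columns, so the fallback fixed with that design was used, and scaling to the 75th percentile became an alternative. The fallback is background correction by normexp with an offset of 50 on mean foreground and median local background over all spots, quantile normalization over the non-control spots, log2, and the mean of the spots of a probe. No spot carries a flag in the files. A probe counted as above background where its background-subtracted signal exceeded the median of 77 negative control spots by 2 SD, and 5863 genes above background on all arrays of at least 1 group were tested, 5003 of them above background on all 12. A spot counted as saturated with at least 50% saturated pixels. One limma model (limma 3.58.1 in R 4.3.3) with 4 group means and 8 residual degrees of freedom gave 6 comparisons, with empirical Bayes variances (prior degrees of freedom 5.53) and Benjamini-Hochberg adjustment within each comparison at 0.05. Gene lists, also fixed before the data were examined, were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 33 lists of a comparison. Some lists share members, so their calls are not separate evidence. SDH1 to SDH4 stand in the tricarboxylic acid cycle and respiratory lists, and GRE1 and HSP12 in the Msn2/Msn4 and stationary phase lists. The lists were the DJ-1 superfamily, autophagy core genes, vacuolar hydrolases, trehalose and glycogen metabolism, the tricarboxylic acid cycle, the glyoxylate cycle and gluconeogenesis, the respiratory chain and ATP synthase, the mitochondrial ribosome, glycolysis and fermentation, hexose transport and sensing, peroxisomes and fatty acid oxidation, heat shock proteins and chaperones, oxidative stress defence, methylglyoxal metabolism, Msn2/Msn4 general stress genes, stationary phase genes, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, nutrient signalling, nitrogen catabolite repressed genes, Gcn4 targets of amino acid biosynthesis, sulfur amino acid synthesis, ergosterol synthesis, the iron regulon, the proteasome, cell cycle and histones, the cell wall, the PAU family, mating type specific genes, meiosis and sporulation, strain markers and mitochondrially encoded genes.

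Genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and falls per comparison with wild type and the 5 largest per comparison between deletions, among genes with a standard name and past the threshold whose 3 arrays all lie beyond the other 3. It adds up to 4 members per list, the targeted genes with SNO4, and the 10 largest changes per direction called in all 3 deletions. Slides were inferred from repeated positions and from scan offsets in the files: wild type replicates 1 and 3, hsp31 deletion 1 and 2, hsp32 deletion 1 and hsp33 deletion 3 on slide 1, and the other 6 arrays on slide 2, each with all 4 groups. Replicate numbers were not taken to pair the samples. With group means removed, arrays of the same number correlated at a mean r of 0.035, -0.033 and -0.013 for numbers 1, 2 and 3. Yet 6 of the 12 arrays correlated best with arrays of their own number in other groups, so pairing is not excluded. Correlation between 2 deletions was set against 100 simulations of unchanged groups built from the spread between arrays. Alternatives were other scalings, the authors' series values, other filters on dim probes, slide or replicate number as a block, array weights, a robust trend in the variances, the 6 arrays of each comparison alone, each slide alone, other thresholds and each array left out in turn. Groups of 3 are too small for a test of outlying samples, which was not made. The limma fit was tested on simulated normalized values for the hsp31 deletion against wild type. Of 67 genes changed 1.5-fold 58 were recovered (86.6%), of 67 changed 2-fold 65 and of 66 changed 4-fold 65, with 4 false calls (2.08% of calls). The noise was independent between genes, 5663 of 5863 genes were unchanged, and background correction and normalization were not rerun. These rates therefore hold for the fit alone and not for comparisons in which most genes change. The authors' sheets of up- and downregulated genes and of functional annotation were left out, since they repeat the comparison tables or have damaged decimals, as were lists of names without values.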

Results

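Messenger RNA levels were measured in budding yeast (Saccharomyces cerevisiae) on 12 one-colour arrays, 3 from wild-type cells and 3 from each of 3 strains labelled as lacking HSP31, HSP32 or HSP33. These genes encode members of the DJ-1 superfamily, and Hsp31 is known as a methylglyoxalase and chaperone. Per the labels, the cells came from synthetic complete medium at the diauxic shift, the time at which glucose runs out and fermenting cells turn to respiration. The comparisons ask which genes differ at that time between each deletion and wild type, and between the deletions. Median spot brightness per array ran from 607 to 1153 over a local background of 66 to 93, and 80.3% to 97.1% of the gene probes stood above the negative controls. The number of arrays limits the precision. The arrays of a group correlated at r = 0.980 to 0.997 across genes, which are not independent replicates. Component 1 of a principal component analysis held 74.0% of the variance and set the wild-type arrays at one end, the hsp32 deletion arrays at the other, and those of the hsp31 and hsp33 deletions between them. Log2 changes are given ± the standard error of the limma fit with 3 arrays per group, and group levels ± SD. Each adjusted p measures only the spread between these samples, which may be technical, since the labels do not say whether the 3 samples of a group came from separate cultures. The reference table gives no chromosome positions, so genes are identified by name and locus.

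HSP31 (YDR533C) carried the label check for the hsp31 deletion. Its normalized log2 signal was 12.65 ± 0.14 in wild type (SD, n = 3) and 6.65 ± 0.15 in the hsp31 deletion, below the background threshold on all 3 arrays. The transcript was at least 44.6-fold lower. Here and below, at least marks a bound, computed from the background threshold of a dim group or from a saturated group. HSP31 was higher in the arrays labelled hsp32 deletion (1.48-fold, log2 0.56 ± 0.10) and hsp33 deletion (1.40-fold, log2 0.48 ± 0.10), both past limma. Under median scaling these rises were 0.15 and 0.10 and no longer passed. HSP32 (YPL280W), HSP33 (YOR391C) and SNO4 (YMR322C), near-identical genes at chromosome ends whose probes may share signal, fell together in all 3 deletions. HSP32 fell by 1.11 ± 0.12, 2.33 ± 0.12 and 1.48 ± 0.12 on the log2 scale in the hsp31, hsp32 and hsp33 deletions. The matching falls of HSP33 were -1.23 ± 0.10, -2.21 ± 0.10 and -1.74 ± 0.10 (log2), with SNO4 at -1.05 ± 0.10, -2.27 ± 0.10 and -1.64 ± 0.10. Both HSP32 and HSP33 stayed above background on all arrays of their own deletion. HSP33 was lower in the hsp32 deletion (log2 8.90 ± 0.11) than in the hsp33 deletion (9.37 ± 0.042). These probes therefore give no check of the hsp32 and hsp33 labels, and the arrays are named below as labelled.

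**Figure D1:**
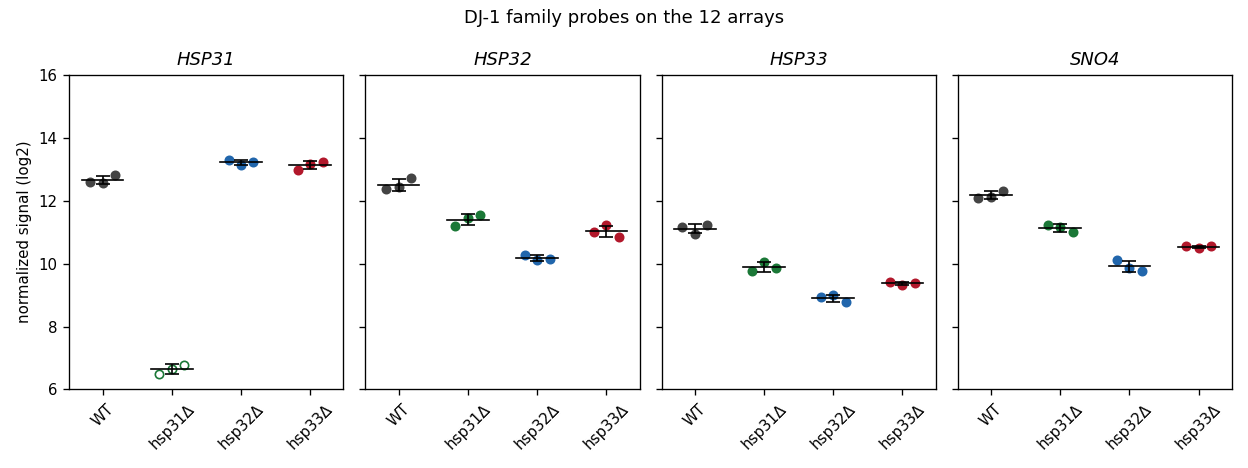
Normalized log2 signal of HSP31, HSP32, HSP33 and SNO4 on each of the 12 arrays (points, by group on the x axis), with the mean and SD of each group of 3 as black lines. Open points lie below the array's background threshold. HSP31 lies below background on the 3 hsp31 deletion arrays alone, at 6.65 ± 0.15 against 12.65 ± 0.14 in wild type, and the 3 near-identical genes are lower in every deletion than in wild type.

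In the hsp31 deletion HXK2, ZRT1 and MIG2 were among the largest rises. HXK2 (YGL253W), hexokinase 2, was 7.36-fold higher (log2 2.88 ± 0.087). The glucose-induced repressor MIG2 was 6.83-fold higher (log2 2.77 ± 0.11) and the hexose transporter HXT4 6.37-fold higher (log2 2.67 ± 0.17). HXT3, another hexose transporter, was at least 4.69-fold higher, a bound because its spots were saturated on all 3 deletion arrays. ZRT1, the high-affinity zinc transporter, was 7.05-fold higher (log2 2.82 ± 0.10) and the zinc-regulated gene ZPS1 5.93-fold higher (log2 2.57 ± 0.088). GLN1, glutamine synthetase, was 6.09-fold higher (log2 2.61 ± 0.15). The other genes with the largest rises were REE1 (log2 2.52 ± 0.090), the flavohemoglobin gene YHB1 (2.24 ± 0.12) and the NADPH oxidoreductase gene OYE2 (2.21 ± 0.10). The mitochondrial GTP carrier gene GGC1 (2.13 ± 0.14) and the ribosomal protein gene RPL12B (4.01-fold) completed the 12 largest fitted rises among genes with a standard name. Beside HSP31 itself, the largest fitted fall was that of the hydrophilin gene GRE1 (YPL223C), 15.9-fold lower (log2 -3.99 ± 0.12). SIP18, also a hydrophilin gene, was 7.33-fold lower (log2 -2.88 ± 0.11). ALD3, a stress-induced aldehyde dehydrogenase, was 9.38-fold lower (log2 -3.23 ± 0.10) with its spots saturated on 1 wild-type array. SPS100, a spore wall gene, was 8.81-fold lower (log2 -3.14 ± 0.095). The pentose phosphate genes GND2 (-2.87 ± 0.14), TKL2 (-2.86 ± 0.12) and SOL4 (-2.18 ± 0.16) fell as well. So did SHH3 (-3.06 ± 0.13), HBT1 (-2.57 ± 0.29), the fatty acid thiolase gene POT1 (-2.39 ± 0.13) and the Hsp70 gene SSA3 (-2.34 ± 0.12). All of these passed limma, with adjusted p of 5.87e-06 (HBT1) or below.

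Among the gene lists, those of protein synthesis, amino acid, ergosterol, cell cycle, cell wall and mating type genes moved up. The 9 lists described next had adjusted p of 2.39e-42 to 0.0352 in limma camera, and adjusted p = 0.0593 to 0.319 with an estimated correlation. Of the 138 cytosolic ribosomal protein genes 136 rose (median log2 1.14), with RPL22A at log2 1.87 ± 0.17 and RPS24A at 1.87 ± 0.11. Ribosome biogenesis followed with 101 of 113 members higher (median log2 0.63), among them SPB1 (1.54 ± 0.30), NOP13 (1.41 ± 0.16) and KRI1 (1.35 ± 0.12). Subunits of RNA polymerases I and III were higher in 13 of 22 cases (median log2 0.39). Amino acid synthesis under Gcn4, the general control activator, rose in 45 of 47 genes (median log2 0.97), with ASN1 at 1.92 ± 0.16 and HIS7 at 1.88 ± 0.14. Sulfur amino acid synthesis rose in 18 of 25 (median log2 0.65), led by CYS3 (1.79 ± 0.084) and the sulfate transporter gene SUL1 (1.74 ± 0.14). Ergosterol synthesis rose in 17 of 26 (median log2 0.53), led by ERG3 (1.78 ± 0.085) and ERG2 (1.71 ± 0.11). The list of cell cycle and histone genes had 22 members higher and 5 lower (median log2 0.39), with the G1 cyclin genes CLN1 (1.47 ± 0.085) and PCL1 (1.40 ± 0.10) among the rises. The cell wall list had 13 higher, GAS1 (1.70 ± 0.11) first, and 5 lower (median log2 0.28). Its call was lost in 3, and that of the cell cycle list in 1, of the 23 alternatives in which the lists were tested again. Among mating type specific genes 7 of 11 rose (median log2 0.83), including the a-factor genes MFA1 (1.59 ± 0.10) and MFA2 (1.39 ± 0.16).

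Stress, reserve and breakdown genes fell. The 9 lists described next had adjusted p of 1.31e-11 to 0.0207 in limma camera, and adjusted p = 0.0593 to 0.342 with an estimated correlation. The general stress genes under Msn2 and Msn4, the stress-responsive transcription factors, fell in 31 of 37 cases (median log2 -0.93), and the stationary phase list in 20 of 29 (median log2 -0.40). All 24 measured genes of the PAU family, near-identical subtelomeric genes of the seripauperins whose probes may share signal, fell (median log2 -0.66). Here and below, their count and camera call may therefore rest on few separate signals. Methylglyoxal genes fell in 8 of 8 cases (median log2 -0.80), with the glyoxalase gene GLO1 at -1.63 ± 0.15 and GRE2 at -0.90 ± 0.12. Heat shock and chaperone genes fell in 22 of 30 cases (median log2 -0.46), among them the Hsp40 gene SIS1 (-1.34 ± 0.095) and HSP82 (-1.29 ± 0.12). The proteasome list fell in 29 of 35 (median log2 -0.41), with RPT6 at -0.95 ± 0.12. Autophagy core genes fell in 29 of 38 (median log2 -0.47), among them ATG33 (-1.23 ± 0.10), ATG40 (-1.08 ± 0.10) and ATG36 (-1.07 ± 0.13), which encode mitophagy, ER-phagy and pexophagy factors. ATG41 rose (1.56 ± 0.092). Adjusted over the list alone, 33 autophagy genes fell. Under that adjustment 20 of the 33 lists kept their counts of rises and falls, the others moving by at most 4 genes. Vacuolar hydrolase genes fell in 8 of 14 (median log2 -0.43), with the mannosidase gene AMS1 at -1.31 ± 0.15. Trehalose and glycogen genes fell in 15 of 21 (median log2 -0.57), with the debranching enzyme gene GDB1 at -1.50 ± 0.19.

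Lists of respiration, carbon recovery, oxidative stress defence and nutrient signalling moved down in part of their members. Falls numbered 9 of 18 in the tricarboxylic acid cycle (median log2 -0.28, with SDH2 at -0.82 ± 0.11) and 12 of 20 in the glyoxylate cycle and gluconeogenesis (-0.58, with ACS1 at -1.27 ± 0.16). There were 16 of 40 in the respiratory chain and ATP synthase (-0.25, with CYB2 at -1.80 ± 0.11) and 18 of 34 in peroxisomes and fatty acid oxidation (-0.22, with CTA1 at -1.33 ± 0.13). They numbered 18 of 35 in oxidative stress defence (-0.23, with GPX1 at -1.80 ± 0.12) and 27 of 52 in nutrient signalling (-0.27, with YAK1 at -1.07 ± 0.20). These 6 lists passed limma camera with adjusted p of 0.00419 to 0.0288, against 0.144 to 0.454 as adjusted p with an estimated correlation. The call of the tricarboxylic acid cycle was lost in 1 alternative. Opposite members stood in the respiratory list, where the cytochrome c gene CYC1 rose (1.12 ± 0.094) while its isoform CYC7 fell (-1.39 ± 0.15). The DJ-1 superfamily list fell in 4 of 4 genes (median log2 -1.17, limma camera adjusted p = 2.53e-04, and adjusted p = 0.0655 with an estimated correlation). In every deletion this list holds the deleted gene and near-identical genes whose probes may share signal, so its calls carry little weight. Strain marker genes had a median of 0.23 (limma camera adjusted p = 0.0435, and adjusted p = 0.144 with an estimated correlation), which turned to -0.036 under median scaling, and their call held in 16 of 23 alternatives. LEU2 (1.09 ± 0.12), MET17 (1.62 ± 0.12) and HIS3 (0.96 ± 0.12) rose. The arginine permease gene CAN1 fell (-0.57 ± 0.19), a fall that did not pass in 5 alternatives.

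No camera call was made for the remaining 7 lists, whose limma camera adjusted p ran from 0.0632 to 0.689. Glycolysis and fermentation held 11 rising and 7 falling genes of 23 (median log2 0.21, turning to -0.049 under median scaling), with the phosphofructokinase activator gene PFK27 at 1.56 ± 0.13 and PDC6 at -1.26 ± 0.12. Hexose transport and sensing held 6 rising and 4 falling genes of 17 (0.074), with HXT5, a transporter of slow growth, at -1.26 ± 0.15. The iron regulon held 8 rising and 7 falling genes of 30 (0.019), with FTR1 at 1.21 ± 0.10 and FIT1 at -1.27 ± 0.11. Nitrogen catabolite repressed genes held 6 rising and 9 falling genes of 31 (-0.079), the mitochondrial ribosome 3 rising and 17 falling genes of 71 (-0.12), and meiosis and sporulation 2 rising and 5 falling genes of 17 (-0.023). These 3 medians turned positive under 75th percentile scaling. Of 8 mitochondrially encoded genes 2 fell, VAR1 (-0.58 ± 0.16) and COX3 (-0.49 ± 0.13), with a list median of -0.055. With 1 array left out, the medians of hexose transport (-0.068 to 0.13), iron (-0.012 to 0.16), meiosis (-0.14 to 0.048) and mitochondrially encoded genes (-0.15 to 0.085) took both signs.

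Against wild type 3290 of 5863 genes passed limma at an adjusted p under 0.05, 1507 higher and 1783 lower. Of these 1424 changed at least 1.5-fold. In this and in the other comparisons with wild type no list passed camera with an estimated correlation: the lowest adjusted p was 0.0593, 0.0739 and 0.0505 in the hsp31, hsp32 and hsp33 deletions. At an unadjusted p under 0.05 that test passed 13, 13 and 10 lists. Limma's fry, which tests whether a list moves one way on balance, called 30, 32 and 30 of 33. Fry does not compare a list with the other genes. Since 3290, 4105 and 3600 of 5863 genes changed, its calls do not set a list apart from the rest. For the hsp31 deletion 2129 genes passed within slide 1 (2 arrays against 2), against 3279 with the slide as a block. Slide 2 holds 1 array of each of these groups. Within slide 1 the ribosomal protein median was 1.13 and the Msn2/Msn4 median -0.94. Direction splits follow the scaling: 45.8% of the changed genes were higher under quantile normalization and 61.1% under scaling to each array's 75th percentile. That scaling moved the median of all genes to 0.12 (log2).

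In the arrays labelled hsp32 deletion the marker gene URA3 (YEL021W), of uracil synthesis, showed the largest change, at least 219-fold higher than wild type, where it lay below background. Large rises were also those of GLN1, ZRT1 and ASN1. GLN1 was 13.4-fold higher (log2 3.74 ± 0.15) and ZRT1 12.5-fold higher (log2 3.65 ± 0.10). MIG2 was 8.99-fold higher (log2 3.17 ± 0.11), HXK2 7.05-fold higher (log2 2.82 ± 0.087) and HXT4 7.04-fold higher (log2 2.82 ± 0.17). ASN1, asparagine synthetase, was 9.47-fold higher (log2 3.24 ± 0.16), and HIS7, of histidine synthesis, 8.06-fold higher (log2 3.01 ± 0.14). The glycerol phosphatase gene GPP1 was 8.66-fold higher (log2 3.11 ± 0.15). GND1, the major 6-phosphogluconate dehydrogenase, was 7.57-fold higher (log2 2.92 ± 0.11), with YHB1 at log2 2.91 ± 0.12 and the kinase gene SKS1 at 2.85 ± 0.14. GRE1 had the largest fitted fall and was 33.2-fold lower (log2 -5.05 ± 0.12), while HBT1 was 18.6-fold lower (log2 -4.21 ± 0.29) and TKL2, a transketolase, 16.6-fold lower (log2 -4.05 ± 0.12). SPS100 was 16.5-fold lower (log2 -4.05 ± 0.095), POT1 16.4-fold lower (log2 -4.03 ± 0.13) and ALD3 15.5-fold lower (log2 -3.96 ± 0.10), the last with saturated spots on 1 wild-type array. Falls followed in SHH3 (-3.68 ± 0.13) and the stationary phase gene SPG1 (-3.63 ± 0.10). SIP18 fell to below background on 1 of the 3 deletion arrays, so no size is given. The proteinase A inhibitor gene PAI3 (-3.37 ± 0.11), SOL4 (-3.30 ± 0.16) and PHM7 (-3.27 ± 0.19) fell too, all with a limma adjusted p of 1.48e-08 or below.

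In the hsp32 deletion arrays 9 lists, of protein synthesis, amino acid, ergosterol, cell cycle, cell wall and mating type genes, moved up. They had adjusted p of 1.21e-36 to 0.0242 in limma camera, and adjusted p = 0.0784 to 0.212 with an estimated correlation. Higher were 137 of 138 cytosolic ribosomal protein genes (median log2 1.73), 111 of 113 of ribosome biogenesis (median log2 1.46) and 16 of 22 polymerase subunit genes (median log2 0.82). Examples were RPL37A (2.64 ± 0.12), the nucleolin-like gene NSR1 (2.81 ± 0.21) and RPA135 (1.86 ± 0.11). All 47 Gcn4 genes rose (median log2 1.47), as did 20 of 25 sulfur amino acid genes (median log2 1.12). Ergosterol genes rose in 20 of 26 (median log2 0.80), with ERG11, the lanosterol demethylase gene, at 2.51 ± 0.14. Cell cycle (21 rose and 9 fell of 38), cell wall (19 rose and 6 fell of 30) and mating type genes (7 rose and 1 fell of 11) had medians of 0.28, 0.51 and 1.08. Calls of the cell cycle and cell wall lists were lost in 3 and 2 of 23 alternatives. Strain marker genes (median log2 1.33, limma camera adjusted p = 0.0207, and adjusted p = 0.114 with an estimated correlation) passed, a call lost in 1 alternative. Besides URA3, MET17 (2.39 ± 0.12), LEU2 (1.85 ± 0.12) and HIS3 (1.33 ± 0.12) were higher.

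Falls in the hsp32 deletion arrays covered 34 of 37 Msn2/Msn4 genes (median log2 -1.97), 22 of 29 stationary phase genes (-0.77) and 20 of 21 trehalose and glycogen genes (-1.44, with the phosphoglucomutase gene PGM2 at -2.14 ± 0.15). They covered 17 of 20 genes of the glyoxylate cycle and gluconeogenesis (-1.70, with the acetyl-CoA synthetase gene ACS1 at -2.94 ± 0.16 and the malate dehydrogenase gene MDH2 at -2.74 ± 0.14). Autophagy core genes fell in 33 of 38 cases (-0.70), with ATG34 at -2.12 ± 0.12, the nuclear and ER autophagy receptor gene ATG39 at -2.11 ± 0.13 and ATG33 at -2.01 ± 0.10. ATG41 rose (1.88 ± 0.092). Vacuolar hydrolases fell in 11 of 14 (-1.12), the tricarboxylic acid cycle in 14 of 18 (-0.78) and the respiratory chain in 30 of 40 (-0.62, with NDE2 at -3.08 ± 0.14). Peroxisomal genes fell in 23 of 34 (-0.55) and oxidative stress defence in 21 of 35 (-0.70, with GTT1 at -2.73 ± 0.13). The proteasome fell in 31 of 35 (-0.61), the PAU family in 23 of 24 (-0.83) and methylglyoxal genes in 8 of 8 (-1.24, with GLO1 at -2.59 ± 0.15). Nutrient signalling fell in 31 of 52 (-0.35). These 14 lists passed limma camera, with adjusted p of 1.28e-12 to 0.00575, against 0.0739 to 0.208 as adjusted p with an estimated correlation. The DJ-1 list had 3 members lower and HSP31 higher (limma camera adjusted p = 0.0484, and adjusted p = 0.219 with an estimated correlation), and its call held in 14 of 23 alternatives.

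Heat shock and chaperone genes moved both ways in these arrays, 7 up and 15 down (median log2 -0.23), and the list did not pass limma camera (adjusted p = 0.150). HSP12, a membrane-protecting small heat shock gene, fell (-3.17 ± 0.19) and the Hsp70 gene SSA2 rose (1.78 ± 0.17). Medians without a call were -0.45 for nitrogen catabolite repressed genes, -0.43 for mitochondrially encoded genes, -0.22 for meiosis, -0.13 for the mitochondrial ribosome, -0.058 for the iron regulon, 0.062 for hexose transport and 0.32 for glycolysis. The last 2 turned negative under median scaling, and those of meiosis, the mitochondrial ribosome and iron turned positive under 75th percentile scaling. With 1 array left out, the medians of hexose transport (-0.012 to 0.11) and iron (-0.10 to 0.023) took both signs. In all 4105 of 5863 genes passed limma at an adjusted p under 0.05, 1953 higher and 2152 lower. Of these 2420 changed at least 1.5-fold. By slide 2626 genes passed within slide 1 (1 array against 2) and 3167 within slide 2 (2 against 1), against 4021 with the slide as a block. Within slides the ribosomal protein median was 1.71 on slide 1 and 1.74 on slide 2 and the Msn2/Msn4 median -1.86 on slide 1 and -2.08 on slide 2. As for the hsp31 deletion, 47.6% of the changed genes were higher under quantile normalization and 61.3% under scaling to each array's 75th percentile. That scaling moved the median of all genes to 0.17 (log2).

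In the arrays labelled hsp33 deletion, the largest fitted change in each direction was that of a mating type gene. MF(ALPHA)1 (YPL187W), the alpha-factor gene, was at least 31.9-fold higher, and STE3, the a-factor receptor gene, 5.32-fold higher (log2 2.41 ± 0.11). HMRA1 (YCR097W), whose probe also matches the MATa1 transcript of a cells, was at least 45.1-fold lower. The pheromone-induced gene AGA1 was 7.81-fold higher (log2 2.97 ± 0.10) and FUS1 5.18-fold higher (log2 2.37 ± 0.093). Of the 11 mating type specific genes all changed, 5 up and 6 down. This left a median of -0.92 but a mean of 0.36 and no camera call (limma adjusted p = 0.983). Of the other large rises, MIG2 was 8.43-fold higher (log2 3.08 ± 0.11), ZRT1 7.88-fold higher (log2 2.98 ± 0.10), GLN1 7.65-fold higher (log2 2.94 ± 0.15) and HXK2 7.64-fold higher (log2 2.93 ± 0.087). With them rose ZPS1 (log2 2.67 ± 0.088), HXT4 (2.62 ± 0.17), HIS7 (2.38 ± 0.14) and REE1 (2.38 ± 0.090). GRE1 was 24.3-fold lower (log2 -4.60 ± 0.12), SPS100 14.8-fold lower (log2 -3.89 ± 0.095) and SHH3 10.1-fold lower (log2 -3.34 ± 0.13). ALD3, with 1 saturated wild-type array, was 9.77-fold lower (log2 -3.29 ± 0.10). Falls also stood at -3.23 ± 0.29 for HBT1, -3.22 ± 0.12 for TKL2, -3.15 ± 0.13 for POT1 and -3.12 ± 0.11 for SIP18 (log2). They stood at -2.94 ± 0.10 for SPG1, -2.71 ± 0.14 for GND2 and -2.66 ± 0.11 for PAI3 (log2). The histidine gene HIS3, a strain marker, fell (-1.33 ± 0.12). Each of these genes passed limma with an adjusted p of 3.93e-07 or below.

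Ribosomal protein genes rose in 137 of 138 cases (median log2 1.47, with RPS16B at 2.15 ± 0.11), ribosome biogenesis in 108 of 113 (0.89, with KRI1 at 1.77 ± 0.12) and polymerase subunits in 16 of 22 (0.49). Gcn4 amino acid genes rose in 45 of 47 (1.09, with BAT1 at 1.94 ± 0.12). Sulfur amino acid genes rose in 19 of 25 (0.87, with MET16 at 1.71 ± 0.089), and ergosterol genes in 19 of 26 (0.70, with ERG25 at 1.81 ± 0.094). Cell cycle (20 rose and 7 fell of 38) and cell wall genes (16 rose and 7 fell of 30) had medians of 0.31 and 0.31. For these 8 lists limma camera gave adjusted p of 4.86e-42 to 0.0306, and adjusted p = 0.0664 to 0.297 with an estimated correlation. The calls of the cell cycle and cell wall lists were lost in 2 alternatives each. Downward lists included the Msn2/Msn4 genes with 33 of 37 lower (-1.28), the glyoxylate cycle and gluconeogenesis with 16 of 20 (-0.93, with CAT2 at -2.21 ± 0.17) and trehalose and glycogen with 18 of 21 (-0.77). Others were vacuolar hydrolases with 10 of 14 (-0.74, with ATH1 at -1.75 ± 0.11) and stationary phase genes with 20 of 29 (-0.71). Autophagy core genes fell in 32 of 38 (-0.55, with ATG39 at -1.72 ± 0.13), while ATG41 rose (1.62 ± 0.092). All 8 methylglyoxal genes fell (-0.98, with GLO1 at -2.17 ± 0.15).

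Falls also covered 32 of 35 proteasome genes (-0.51 as median log2), 24 of 24 PAU genes (-0.63), 13 of 18 genes of the tricarboxylic acid cycle (-0.44) and 22 of 40 of the respiratory chain (-0.34). Lower too were 21 of 34 of peroxisomes (-0.37), 19 of 35 of oxidative stress defence (-0.30) and 28 of 52 of nutrient signalling (-0.32). Falls stood in 17 of 30 heat shock and chaperone genes (-0.33, with HSP26 at least 2.14-fold lower, saturated on all 3 wild-type arrays). The 15 downward lists had limma camera adjusted p of 4.75e-12 to 0.00974, and adjusted p = 0.0505 to 0.260 with an estimated correlation. The DJ-1 list passed with an adjusted p of 0.0456 in limma camera and adjusted p = 0.250 with an estimated correlation. It had 3 genes lower and HSP31 higher and kept the call in 15 of 23 alternatives. Medians without a call were 0.40 for glycolysis, -0.059 for hexose transport, -0.031 for iron, -0.29 for nitrogen genes and -0.25 for mitochondrially encoded genes. They were -0.17 for meiosis, -0.044 for the mitochondrial ribosome and 0.064 for strain markers. Those of hexose transport, iron, meiosis and the mitochondrial ribosome turned positive under 75th percentile scaling and that of strain markers negative under median scaling. The iron median ran from -0.049 to 0.016 with 1 array left out. In total 3600 of 5863 genes passed limma at an adjusted p under 0.05, 1700 higher and 1900 lower. Of these 1763 changed at least 1.5-fold. By slide 2226 genes passed within slide 1 (1 array against 2) and 2261 within slide 2 (2 against 1), against 3515 with the slide as a block. Within slides the ribosomal protein median was 1.66 on slide 1 and 1.36 on slide 2 and the Msn2/Msn4 median -1.38 on slide 1 and -1.32 on slide 2. Here too 47.2% of the changed genes were higher under quantile normalization and 61.8% under scaling to each array's 75th percentile. That scaling moved the median of all genes to 0.15 (log2).

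**Figure D2:**
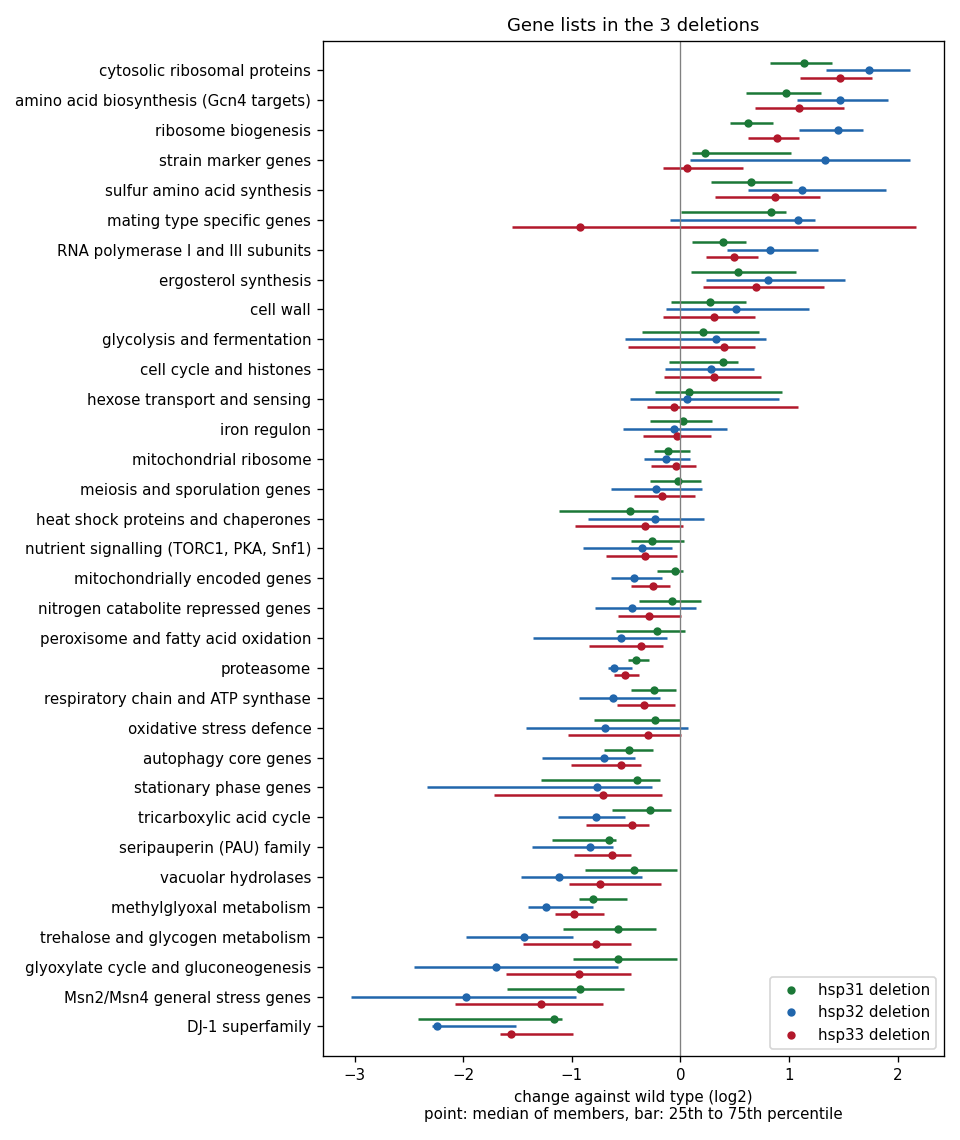
Change against wild type (log2, x axis) of the 33 gene lists (y axis, ordered by the hsp32 deletion) in the 3 deletions, with points for the median of the members and bars from the 25th to the 75th percentile. Ribosomal proteins lie at 1.14, 1.73 and 1.47 and the Msn2/Msn4 genes at -0.93, -1.97 and -1.28 in the hsp31, hsp32 and hsp33 deletions. Medians near 0 change sign with the scaling, as for glycolysis, hexose transport, iron, nitrogen genes, meiosis, the mitochondrial ribosome and strain markers.

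The 3 deletions shared most of their changes. ZRT1, GLN1, MIG2, HXK2, HXT4, ZPS1, REE1, YHB1, OYE2 and ASN1 were the 10 genes with a standard name and the largest mean fitted rise among those called in all 3. GRE1, SPS100, ALD3, TKL2, SHH3, HBT1, POT1, SIP18, GND2 and SPG1 had the largest mean fitted falls. Averaged over the deletions, ZRT1 rose by 3.15 and GRE1 fell by 4.55 on the log2 scale. Limma called 1320 genes higher and 1490 lower in all 3 deletions, where independent calls would give 146 and 212. The hsp31 and hsp32 deletions shared 1392 rises and 1592 falls (expected 502 and 654), and the hsp31 and hsp33 deletions 1357 and 1543 (437 and 578). The hsp32 and hsp33 deletions shared 1601 and 1785 (566 and 697). In these pairs 10, 12 and 16 genes were called in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at r = 0.897 (hsp31 and hsp32), 0.906 (hsp31 and hsp33) and 0.931 (hsp32 and hsp33), with rho = 0.901, 0.916 and 0.952. Part of this can come from the 3 wild-type arrays common to all comparisons, which cannot be divided into groups of at least 2. Simulated unchanged groups with a shared control of 3 gave a mean r of 0.453, 0.479 and 0.429 and a highest r of 0.871, 0.924 and 0.871. The simulated control was drawn from the spread within groups of all 12 arrays, not from the wild-type arrays alone. Median SD (log2) was 0.085 in wild type and 0.107 to 0.124 in the deletions. The r between the hsp31 and hsp33 deletions lies below the highest simulated one. The covariances of 0.453, 0.360 and 0.562 compare with at most 0.0282, 0.0300 and 0.0284 in the simulations.

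Between the hsp32 and hsp31 deletions the shared shift differed in size. In the hsp32 deletion URA3 was higher, with 2 of the 3 hsp31 deletion arrays below background, so no size is given. HSP31 was at least 65.8-fold higher than in its own deletion. GPP1 was 3.28-fold higher (log2 1.72 ± 0.15), NSR1 3.23-fold higher (log2 1.69 ± 0.21) and SSA2 3.11-fold higher (log2 1.63 ± 0.17). MDH2, of gluconeogenesis, was 3.79-fold lower (log2 -1.92 ± 0.14), and RGI2, a respiratory growth gene, 3.65-fold lower (log2 -1.87 ± 0.16). The acetate transporter gene ADY2 was 3.54-fold lower (log2 -1.82 ± 0.19), HSP12 3.43-fold lower (log2 -1.78 ± 0.19) and the drug transporter gene PDR15 3.31-fold lower (log2 -1.73 ± 0.20). HSP32 (log2 -1.23 ± 0.12), HSP33 (-0.99 ± 0.10) and SNO4 (-1.22 ± 0.10) were lower too. The 8 lists described next had adjusted p of 1.20e-29 to 3.70e-04 in limma camera, and adjusted p = 0.109 to 0.118 with an estimated correlation. Ribosomal protein genes were higher in 117 of 138 cases (median log2 0.58) and ribosome biogenesis genes in 102 of 113 (median log2 0.82), and Gcn4 genes in 38 of 47 (median log2 0.48). Lower were 30 of 37 Msn2/Msn4 genes (median log2 -0.87) and 16 of 20 genes of the glyoxylate cycle and gluconeogenesis (median log2 -1.12). So were 19 of 21 of trehalose and glycogen (median log2 -0.84) and 19 of 38 of autophagy (median log2 -0.27). Heat shock and chaperone genes went the other way, 16 of 30 being higher in the hsp32 deletion (median log2 0.35). YDJ1, an Hsp40 gene, differed by 1.23 ± 0.11 (log2), with -0.65 ± 0.11 against wild type in the hsp31 deletion and 0.58 ± 0.11 in the hsp32 deletion. HSP82 differed by 0.92 ± 0.12, both genes being chosen after their values were seen.

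Of the 5863 genes tested between the hsp32 and hsp31 deletions, 2206 passed limma at an adjusted p under 0.05, 1163 higher and 1043 lower. Of these 803 changed at least 1.5-fold, and 23 of 33 lists passed camera and none with an estimated correlation (lowest adjusted p = 0.109, limma). Under median scaling 980 were higher and 1068 lower, and under 75th percentile scaling 1352 and 827, so the balance follows the scaling. By slide 459 genes passed within slide 1 (1 array against 2) and 611 within slide 2 (2 against 1), against 2042 with the slide as a block.

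Beside HSP31, the largest fitted differences between the hsp33 and hsp31 deletions were in mating type genes. MF(ALPHA)1 was 19.4-fold higher (log2 4.28 ± 0.12) in the hsp33 deletion, STE3 6.18-fold higher (log2 2.63 ± 0.11). The alpha regulator genes HMLALPHA1 and MATALPHA1, whose probes share sequence, were 5.81-fold higher (log2 2.54 ± 0.13) and 4.88-fold higher (log2 2.29 ± 0.18). HMRA1 was at least 37.8-fold lower, the a-factor genes MFA2 14.3-fold lower (log2 -3.83 ± 0.16) and MFA1 12.2-fold lower (log2 -3.61 ± 0.10). The alpha-factor protease gene BAR1 was 5.88-fold lower (log2 -2.56 ± 0.12) and the alpha-factor receptor gene STE2 4.94-fold lower (log2 -2.30 ± 0.087). HSP31 was at least 62.2-fold higher, HSP33 (log2 -0.51 ± 0.10) and SNO4 (-0.59 ± 0.10) were lower, and HSP32 (-0.37 ± 0.12) did not pass (limma adjusted p = 0.0986). Small shifts of the median, with few members past limma in most, stood in 8 lists with adjusted p of 1.26e-23 to 6.98e-04 in limma camera, and adjusted p = 0.237 to 0.309 with an estimated correlation. Medians were 0.30 for ribosomal proteins (35 of 138 higher), 0.24 for ribosome biogenesis (10 of 113), 0.13 for Gcn4 genes (4 of 47), and 0.22 for heat shock genes (6 of 30). They were -0.31 for Msn2/Msn4 genes (4 of 37 lower), -0.48 for the glyoxylate cycle and gluconeogenesis (7 of 20), -0.26 for trehalose and glycogen (2 of 21) and -0.15 for autophagy (4 of 38). In this comparison 283 of 5863 genes passed limma at an adjusted p under 0.05, 168 higher and 115 lower. Of these 98 changed at least 1.5-fold. Under median scaling 87 were higher and 88 lower, and under 75th percentile scaling 158 and 88, so the balance follows the scaling. By slide 36 genes passed within slide 1 (1 array against 2) and 28 within slide 2 (2 against 1), against 155 with the slide as a block. The count is unsteady, as leaving out 1 array gave 94 genes without hsp31 deletion replicate 2 and 399 without hsp31 deletion replicate 3, and array weights gave 614.

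Against the hsp32 deletion the hsp33 deletion arrays again differed in mating type genes and in URA3. MF(ALPHA)1 was 15.3-fold higher (log2 3.94 ± 0.12). MATALPHA1, HMLALPHA1, STE3 and the other alpha-factor gene, MF(ALPHA)2, were higher too. These 4 lay below background on 1 or 2 of the 3 hsp32 deletion arrays, so no size is given. For STE3 this was replicate 2 alone, the array with the highest threshold (284). STE3 read 8.05 (log2) there and 7.98 on replicate 3, where it counted as above background. URA3 was at least 238-fold lower, HMRA1 at least 29.4-fold lower and MFA2 15.4-fold lower (log2 -3.94 ± 0.16). MFA1 was 11.8-fold lower (log2 -3.56 ± 0.10) and BAR1 6.57-fold lower (log2 -2.72 ± 0.12). HSP32 (log2 0.85 ± 0.12), HSP33 (0.47 ± 0.10) and SNO4 (0.63 ± 0.10) were higher in the hsp33 deletion, and HSP31 did not pass (-0.082 ± 0.10). The shared shift was smaller in the hsp33 deletion, in 7 lists with adjusted p of 3.78e-33 to 0.00239 in limma camera, and adjusted p = 0.111 to 0.249 with an estimated correlation. Here 85 of 113 ribosome biogenesis genes were lower (median log2 -0.54), 43 of 138 ribosomal protein genes (median log2 -0.27) and 32 of 47 Gcn4 genes (median log2 -0.38). Msn2/Msn4 genes were higher in 29 of 37 (median log2 0.56). Higher too were 14 of 21 trehalose and glycogen genes (median log2 0.56), 9 of 20 of the glyoxylate cycle and gluconeogenesis (median log2 0.50) and 7 of 38 of autophagy (median log2 0.16). Between these deletions 1097 of 5863 genes passed limma at an adjusted p under 0.05, 561 higher and 536 lower. Of these 303 changed at least 1.5-fold. Under median scaling 560 were higher and 408 lower, and under 75th percentile scaling 449 and 576, so the balance follows the scaling. By slide 879 genes passed within slide 2 (2 arrays against 2), against 1073 with the slide as a block, and without hsp33 deletion replicate 1 the count was 505. Array weights gave 1696.

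**Figure D3:**
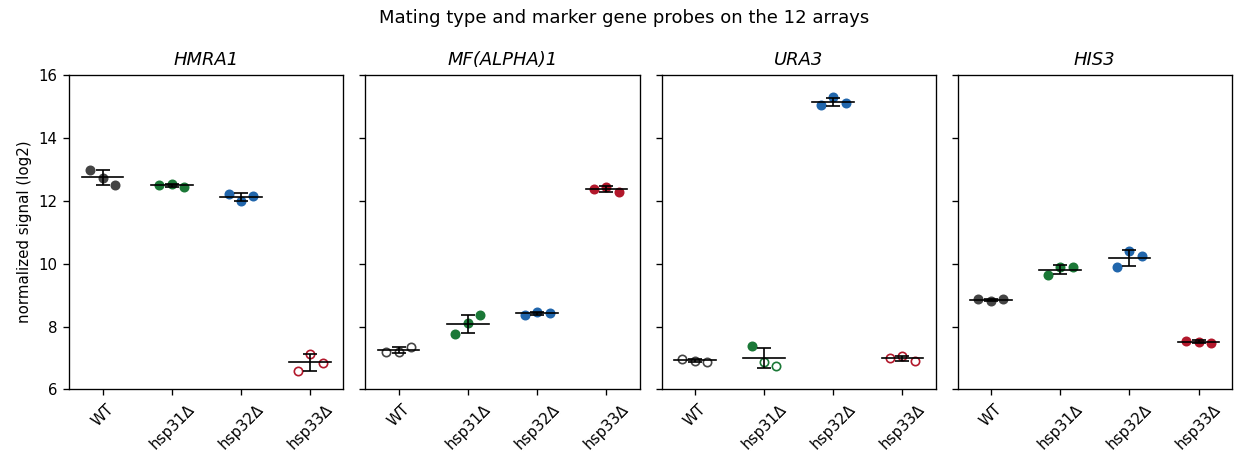
Normalized log2 signal of HMRA1, MF(ALPHA)1, URA3 and HIS3 on each of the 12 arrays (points, by group on the x axis), with the mean and SD of each group of 3 as black lines. Open points lie below the array's background threshold. HMRA1 lies below background and MF(ALPHA)1 at 12.36 ± 0.094 on the 3 hsp33 deletion arrays, URA3 reaches 15.14 ± 0.13 on the 3 hsp32 deletion arrays alone, and HIS3 is lowest in the hsp33 deletion at 7.51 ± 0.043.

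Marker transcripts also differed between the groups. URA3 stood at 6.92 ± 0.046 in wild type (log2, mean ± SD), 15.14 ± 0.13 in the hsp32 deletion and 6.98 ± 0.068 in the hsp33 deletion. It was above background on 1 of the 9 arrays outside the hsp32 deletion. HIS3 stood at 8.84 ± 0.040, 9.80 ± 0.15, 10.18 ± 0.26 and 7.51 ± 0.043 in wild type and the hsp31, hsp32 and hsp33 deletions. LYS2 lay below background on 10 of 12 arrays. Each comparison with the hsp32 or hsp33 deletion therefore also compares arrays that differ in URA3 or in the mating type they express. Between the hsp31 deletion and wild type, URA3 (log2 0.079 ± 0.13) and HMRA1 (-0.25 ± 0.14) did not pass limma. HIS3 (0.96 ± 0.12) and MFA1 (1.59 ± 0.10) were higher there.

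The authors' deposited table of each deletion against wild type lists spots with a p of at most 0.05 from a test that is not stated. Per the authors' deposited table, 2561 loci were lower and 1341 higher in the hsp31 deletion, 2710 and 1567 in the hsp32 deletion, and 2592 and 1478 in the hsp33 deletion. Of the listed loci tested here, 3615 of 3822, 4016 of 4187 and 3831 of 4036 had the same direction in the limma fit, or 94.6%, 95.9% and 94.9%. Past the limma threshold 2777, 3475 and 3089 had the same direction and 23, 41 and 34 the opposite one. The deposited ratios of 1 and above have lost their decimal point, so only their side of 1 was used.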

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

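The other splits of the comparisons with wild type were planned, those between deletions and the tests on scaling, slides, uracil and histidine genes were chosen after the first results but before their own values were seen, and the tests on the covariance, glucose-induced genes and mating type genes were chosen after the results were seen.

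The differences between deletions below were each tested as a comparison of their own in limma. The hsp32 and hsp31 deletions differed in 2206 genes, the hsp33 and hsp31 deletions in 283 and the hsp33 and hsp32 deletions in 1097, with 23, 20 and 21 of the 33 lists past camera at the preset correlation and none at an estimated one. Each comparison of 3 arrays with 3 can be split in 10 ways, too few for a share under 0.05, and in all 6 comparisons only 1 split, the real one, gave as many genes. Every other split mixes both groups on each side, so a difference between the groups widens its spread and lowers its count. The counts of the other splits are therefore not those of unchanged groups. In fits to the 6 arrays alone, the hsp31, hsp32 and hsp33 deletions gave 3262, 4203 and 3940 genes against wild type with at most 0 in the other splits, where limma gave at most 72, 45 and 140 at an unadjusted p under 0.05. The deletions gave 1707 (hsp32 against hsp31), 98 (hsp33 against hsp31) and 855 (hsp33 against hsp32), with at most 0, 2 and 0 in the others and 136, 422 and 459 unadjusted.

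List medians that differed between the hsp32 and hsp31 deletions (log2) were ribosomal proteins 0.58, ribosome biogenesis 0.82, Gcn4 targets 0.48, Msn2/Msn4 genes -0.87, glyoxylate cycle and gluconeogenesis -1.12, trehalose and glycogen -0.84, heat shock genes 0.35, autophagy -0.27. Between the hsp33 and hsp31 deletions the medians were ribosomal proteins 0.30, ribosome biogenesis 0.24, Gcn4 targets 0.13, Msn2/Msn4 genes -0.31, glyoxylate cycle and gluconeogenesis -0.48, trehalose and glycogen -0.26, heat shock genes 0.22, autophagy -0.15, and between the hsp33 and hsp32 deletions ribosomal proteins -0.27, ribosome biogenesis -0.54, Gcn4 targets -0.38, Msn2/Msn4 genes 0.56, glyoxylate cycle and gluconeogenesis 0.50, trehalose and glycogen 0.56, autophagy 0.16. Single genes differed between the hsp32 and hsp31 deletions by these log2 changes: URA3 8.14, HSP31 6.57, GPP1 1.72, NSR1 1.69, SSA2 1.63, MDH2 -1.92, RGI2 -1.87, ADY2 -1.82, HSP12 -1.78, PDR15 -1.73, HSP32 -1.23, HSP33 -0.99, SNO4 -1.22. Between the hsp33 and hsp31 deletions the changes were HSP31 6.48, MF(ALPHA)1 4.28, STE3 2.63, HMLALPHA1 2.54, MATALPHA1 2.29, HMRA1 -5.63, MFA2 -3.83, MFA1 -3.61, BAR1 -2.56, STE2 -2.30, HSP33 -0.51, SNO4 -0.59. Between the hsp33 and hsp32 deletions they were MF(ALPHA)1 3.94, MATALPHA1 2.78, HMLALPHA1 2.67, STE3 2.50, MF(ALPHA)2 2.46, URA3 -8.16, HMRA1 -5.27, MFA2 -3.94, MFA1 -3.56, BAR1 -2.72, HSP32 0.85, HSP33 0.47, SNO4 0.63. Where all 3 arrays of a group lie below background, as for HSP31, HMRA1 and, in the hsp33 against the hsp32 deletion, URA3, the bounds in the report apply in place of these fitted values. URA3 in the hsp32 against the hsp31 deletion has no bound, since 1 hsp31 deletion array lay above background. Its fitted value, and those of MATALPHA1, HMLALPHA1, STE3 and MF(ALPHA)2 in the hsp33 against the hsp32 deletion, rest on a group with 1 or 2 arrays below background and give the direction only.

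The shift shared by the 3 deletions was set against 4 explanations. In it the medians of protein synthesis lists were up and those of stress and respiration lists down, though not all their members passed limma. Array scaling as the whole cause is argued against by the list medians. Those of ribosomal proteins and Msn2/Msn4 genes kept their directions, with at least 0.855 (log2), in every deletion under 3 alternatives. These were 2 other scalings and the authors' series values, which change the intensity used and not the scaling. Slides are argued against too, since both hold all 4 groups, the smallest ribosomal protein median within a slide was 1.13 (hsp31 deletion, slide 1, 2 arrays against 2), and the medians with the slide as a block were 1.14, 1.75 and 1.49. So is the spread between the shared wild-type arrays, since the smallest covariance between 2 deletions was 0.360 and the highest simulated one 0.0300. The simulations hold only the spread within groups, drawn from all groups, so they cannot test an offset common to all 3 wild-type arrays. Collection of the wild-type cultures further into the diauxic shift cannot be told apart from an effect of the deletions, because culture and strain go together and the labels give no density or glucose level: 5 of 6 glucose-induced genes (HXK2, HXT1, HXT3, HXT4 and MIG2, not MIG1) were higher in all 3 deletions. An effect of the deletions stays open with it.

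The mating type genes of the hsp33 deletion arrays were weighed against a mixture of cells, a mislabelled array and a strain of the other mating type. A mixture with a cells is argued against by HMRA1, which allows at most 2.64% of its level in the hsp31 deletion, and a single mislabelled array by 3 of 3 hsp33 deletion arrays having MF(ALPHA)1 above and HMRA1 below every array of the other groups. All 11 listed genes, 6 a-specific ones falling and 5 alpha-specific ones rising, changed against the hsp31 deletion as they would in an alpha strain set against a strains, so a strain of the other mating type may be the source. The labels do not give the mating type, and loss of HSP33 as the cause was not tested apart from it.

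High URA3 in the hsp32 deletion arrays was weighed against uracil limitation, which would raise the other genes under the same activator. URA1, URA4 and URA10 had a median change of -0.156 (log2) against wild type, with -0.16 ± 0.16, 0.19 ± 0.091 and -0.90 ± 0.084. URA1 and URA4 did not pass limma and URA10 fell, which argues against it for these genes. The genes did not move as a set, and URA1 rose in the hsp31 (1.19 ± 0.16) and hsp33 deletions (1.17 ± 0.16), where URA3 did not. A URA3 marker in that strain, whether at the deleted locus or elsewhere, may be the source and was not tested, since the labels do not give the construction. Low HIS3 in the hsp33 deletion arrays was set against lower amino acid control of the histidine genes, which is argued against by the median change of HIS1, HIS4 and HIS5 against the hsp31 deletion, 0.412 (log2).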

How the results depend on the processing

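The 75th percentile scaling, the threshold from the median absolute deviation, each slide alone and the omission of both doubtful arrays were chosen after seeing the data, the others before. Counts of changed genes are given for the comparisons in the order hsp31, hsp32 and hsp33 deletion against wild type, then hsp32 against hsp31, hsp33 against hsp31 and hsp33 against hsp32. With at least 1.5-fold besides the adjusted p they were 1424, 2420, 1763, 803, 98, 303, and with an unadjusted p and 1.5-fold 1430, 2421, 1767, 816, 120, 311, fewer because of the fold limit. Slide 1 alone gave 2129, 2626, 2226, 459, 36, 20 and slide 2 alone 1444, 3167, 2261, 611, 28, 879. On slide 1 these compare 2 arrays with 2, then 1 with 2 in the next 4 and 1 with 1 in the last, and on slide 2 1 with 1, then 2 with 1 in the next 4 and 2 with 2, so counts from 1 array against 1 take their spread from other groups and carry no weight. With replicate number as a block, although the samples were not taken as paired, the counts were 3243, 4058, 3539, 2152, 377, 1088. The hsp33 against hsp31 count was 175 with median scaling, 155 with the slide as a block, 614 with array weights, 154 without hsp31 deletion replicate 1 and hsp32 deletion replicate 2, and 98 with only the 6 arrays compared, where the cause was not tested. Array weights gave 1696 for hsp33 against hsp32, of which the cause was not tested. Leaving out 1 array in turn gave 2860 to 3362, 3788 to 4312, 3270 to 3855, 1838 to 2239, 94 to 399, 505 to 1350. The arrays whose omission moved a count by over 1.5 times were, for hsp33 against hsp31, wild type replicate 1 (178), wild type replicate 2 (175), hsp31 deletion replicate 1 (138), hsp31 deletion replicate 2 (94), hsp33 deletion replicate 2 (98), hsp33 deletion replicate 3 (117) and, for hsp33 against hsp32, hsp33 deletion replicate 1 (505), hsp33 deletion replicate 2 (662). Lists past camera numbered 25 to 27, 24 to 25, 23 to 24 of 33 against wild type with 1 array left out, and 0, 0 and 0 with an estimated correlation (limma), where the cause was not tested. Genes called in all 3 deletions numbered 1164 to 1925 higher and 1211 to 1839 lower over all alternatives, and 1164 to 1397 and 1311 to 1519 with 1 array left out. Correlations of fold changes ran from 0.865 to 0.918, 0.875 to 0.935 and 0.913 to 0.951 over all alternatives, and with 1 array left out from 0.865 to 0.914, 0.875 to 0.923 and 0.913 to 0.936 (hsp31 with hsp32, hsp31 with hsp33, hsp32 with hsp33). Of 10660 values of named genes under the alternatives 10632 kept direction and side of the threshold, 27 lost the call, 1 gained it and 0 reversed. Named genes were largely chosen for large changes past the threshold on these same arrays, so this share does not describe other genes. Not run were the mean of all probes, since each gene has 1 probe, and quantile normalization of a processed signal that the files lack, while normexp with quantile normalization is the reported setting. Signal over background limits fold changes of dim genes, whose bounds rest on the negative controls, and saturation those of the brightest.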

Other observations

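The isozyme pairs and the zinc genes in this part were chosen after the data were seen, and no explanation was tested for them. Enzyme pairs with a member known from fast growth on glucose and a member known from starvation or stress moved apart in part of the pairs tested. Log2 changes in the hsp31, hsp32 and hsp33 deletions were 1.56, 2.92, 2.17 for GND1 and -2.87, -3.10, -2.71 for GND2 (6-phosphogluconate dehydrogenase), 1.91, 2.59, 2.09 for TKL1 and -2.86, -4.05, -3.22 for TKL2 (transketolase), and 1.10, 1.59, 1.15 for SOL3 and -2.18, -3.30, -2.48 for SOL4 (6-phosphogluconolactonase). They were 0.40, 0.68, 0.39 for TAL1 and -1.15, -2.55, -1.79 for NQM1 (transaldolase), and 0.38, 0.53, 0.54 for PDC1 and -1.26, -1.37, -1.15 for PDC6 (pyruvate decarboxylase). Of 14 pairs the growth member was higher and the starvation member lower, both past limma, in 6, 8 and 8, and the opposite held in 0 pairs of each deletion. Among the pairs that did not move apart were HSC82 (-1.05, -0.84, -0.65), which fell with its partner HSP82 (-1.29, -0.36, -0.54), and TDH3 (-0.58, -0.81, -0.75), which fell with TDH1 (-0.37, -0.76, -0.50), and HXK1 and PYK2, the partners of HXK2 and CDC19, were not lower. Of the growth members, ADH1 (0.14, -0.029, -0.012) was not higher past limma in any deletion, ACS2 (0.30, 0.36, 0.14) not in the hsp31 and hsp33 deletions, PGM1 (0.25, 0.21, 0.35) not in the hsp31 and hsp32 deletions, and SSA2 (0.15, 1.78, 1.24) not in the hsp31 deletion.

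ZRT1 stood among the largest rises in all 3 deletions and ZPS1 in the hsp31 and hsp33 deletions. In the hsp31, hsp32 and hsp33 deletions ZRT1, the high-affinity zinc transporter, changed by 2.82 ± 0.10, 3.65 ± 0.10, 2.98 ± 0.10 (log2), ZPS1 by 2.57 ± 0.088, 2.71 ± 0.088, 2.67 ± 0.088, the alcohol dehydrogenase gene ADH4 by 0.85 ± 0.13, 0.90 ± 0.13, 0.83 ± 0.13, the metal transporter gene FET4 by 0.91 ± 0.14, 1.21 ± 0.14, 0.91 ± 0.14 and the other zinc transporter gene ZRT2 by 0.53 ± 0.10, 0.47 ± 0.10, 0.56 ± 0.10. Of 11 genes known to respond to the zinc regulator Zap1, 6, 9 and 8 rose past limma and 0, 1 and 0 fell, DPP1 being the gene that fell in the hsp32 deletion (-0.49 ± 0.085). The vacuolar zinc transporter gene ZRC1 did not pass in any deletion (-0.20 ± 0.087, -0.083 ± 0.087, -0.094 ± 0.087). The list's medians were 0.27, 0.69 and 0.56, ZRT1 and ZPS1 having been seen before the list was made.

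In the authors' deposited autophagy sheet for the hsp31 deletion, 63 of 81 lines set the name of an autophagy gene beside the values of another locus, against 0 of 95 and 0 of 71 in the sheets for the hsp32 and hsp33 deletions. On component 2, which held 9.03% of the variance, hsp31 deletion replicate 1 lay at -23.0 and the other 2 arrays of its group at -7.16 and -5.85, and its mean r with its own group was 0.980.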
